A study of Mus musculus with 20 samples.

How the data were processed

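The series measured polyA RNA of mouse lumbar dorsal root ganglia, the clusters of sensory neuron cell bodies beside the spinal cord. Per the labels, 10 adult C57Bl6 animals gave 2 libraries each, 1 after formalin injection and 1 without injection, 1 month after tamoxifen. By the sample titles, 5 animals were controls carrying floxed Prdm12 alleles and 5 were inducible conditional knockouts (icKO), which also carried an inducible Cre recombinase. The characteristics name an Adv-driven CreERT2 and the series text names a Rosa26-driven one, and both are given here as they stand. Libraries were made with a kit that does not mark the strand, per the labels' protocols, so reads of overlapping genes on opposite strands cannot be told apart.

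The deposited files hold raw counts per Ensembl gene for 55416 genes and carry no header. Per the submitters' processing notes, bcl2fastq 2.20.0.422, STAR 2.7.8a, featureCounts 2.0.1 and the GRCm39 build were used. The annotation release and the settings for strand and for reads with several matches are not given in the sources used here. Gene families with near-identical members, such as the alpha globins Hba-a1 and Hba-a2, the Mrgprb receptors and the immunoglobulin segments, are therefore uncertain at the level of the single gene. Gene names came from a name table that matched 52083 of the IDs (94%). Between 96.06% and 99.59% of a used library's counts fell on named IDs. The annotation at hand is of another build (GRCm38.p6), so no coordinates are printed, and it was used only for names and for which genes neighbour each other.

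Groups follow the sample titles throughout. The genotype in the titles and the genotype word in the names under which the counts were deposited differ for 4 of the 10 animals, those labelled control 1, control 4, icKO 2 and icKO 3. Before the data were examined, each genotype comparison was therefore set up both with all animals by label and with the 6 animals for which both records give the same genotype (control 2, 3 and 5; icKO 1, 4 and 5). The lists, the rule for named genes and the alternatives were also written before the data were examined, apart from 2 alternatives named below.

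The 19 libraries used held 11763893 to 22392635 counts. The library labelled icKO 1 formalin held 2829 counts over 1905 genes and was left out of every main test, although the written design named all 20 libraries; the series text also counts 4 formalin icKO samples. The 36 group values tested for outliers and the sex markers were computed per library, and 0 libraries differed from their sex label. No 2 libraries were identical, and libraries of a group differed by 7.73 to 113 times the sampling variance (chi-square per degree of freedom).

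Counts were tested with edgeR 4.0.16 (quasi-likelihood F test, robust, TMM scaling, filterByExpr, sex as covariate) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. For genotype, the libraries of each animal were summed so that the animal is the replicate ("animal totals"); the total of icKO 1 is its noninjected library alone. Genotype was also tested within each agent, and formalin within each genotype, pooled over genotypes and as an interaction, in fits where the 4 groups share one dispersion. Levels are CPM (counts scaled to 1e+06 per library) after TMM scaling, and standard errors were derived from the fold and the F statistic. Prdm12 was compared over animals by an exact two-sided permutation test of log2 CPM. Gene lists were tested with camera on voom values (limma 3.58.1) with a preset correlation of 0.01 and with an estimated correlation, and with fry. Lists called by fry are counted on its test of movement in one direction. Of 476 list entries, 475 matched a gene.

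Named genes are Prdm12, the 12 genes with the smallest p in each direction past the threshold with a mean log2 CPM of at least 1 (leaving out predicted genes), or the 3 smallest in each direction where none passed. In each list, up to 4 members past the threshold are named, otherwise the 2 with the smallest p. For the other comparisons, up to 5 genes in each direction are named. Of these, the text prints those that bear on the groups it describes. Avil and the genes around it were singled out after their values were seen.

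The alternatives were RLE size factors, DESeq2 1.42.0, no filter beyond a count above 0, no sex term, leaving out each animal, the animal or the title number as a replicate block, limma-voom with the animal as a random effect, fits of only the groups compared and, for the pooled formalin comparison, the 6 agreeing animals alone. Added after the data were seen were fits with the small library and fits without the icKO 5 formalin library, which held skeletal muscle transcripts. Both libraries of an animal carry the same animal number in the deposited names, so formalin and noninjected libraries are paired by animal. As a check, their deviations from the group means correlated at -0.15 (icKO 3) to 0.62 over 9 pairs, 8 of which were over 0.1.

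Tests were tried on simulated counts with 200 changed genes. For animal totals of the 6 animals over 19063 genes, 40% of genes changed 1.5-fold and 74% of genes changed 2-fold were recovered, with 8.8% false calls. For animal totals of all 10 animals over 19441 genes, 55% and 89% of genes changed 1.5-fold and 2-fold were recovered. These simulated changes followed the label in every animal. The shares therefore do not hold for genes that, like Prdm12, go against the label in some animals. For the pooled formalin comparison over 17275 genes these were 81% and 97%. Over 17669 genes, for the noninjected libraries of the 6 animals, 29% and 78% were recovered. In the list test (camera with the preset correlation) simulated for animal totals of the 6 animals over 19063 genes, 1 raised list of 20 genes was called and 0 of 32 other lists were. Genes were drawn independently there. The 0 therefore says nothing about false calls in lists whose members move together, such as skeletal muscle (estimated correlation 0.988 between these animals). Figures were drawn with matplotlib 3.10.9.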

Results

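The series counted transcripts in lumbar dorsal root ganglia (L3 to L5) of adult mice in which Prdm12, a transcription factor gene of the nociceptor lineage, was floxed in the animals labelled control and icKO. Those labelled icKO are inducible knockouts after tamoxifen by their labels. The libraries fall into 4 labelled groups of 5, control and icKO, each with and without formalin, an irritant that causes inflammatory pain. The formalin icKO group had 4 usable libraries. Library totals of the 19 libraries used ran from 11763893 to 22392635 counts. The genotype record differs between the titles and the deposited names for the animals labelled control 1, control 4, icKO 2 and icKO 3, so every direction between genotypes below holds for animals as labelled.

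Prdm12 (ENSMUSG00000079466), the targeted gene, did not separate the animals by their labels. Its level in animal totals was 26 CPM in the animal labelled control 1 and 33.2 CPM in control 4, against 100, 84 and 97.2 CPM in control 2, 3 and 5. Among animals labelled icKO it was 23.3, 18 and 18.4 CPM in icKO 1, 4 and 5, against 73.2 CPM in icKO 2 and 98.3 CPM in icKO 3. Over all animals by label, Prdm12 averaged 68.2 ± 35.8 CPM in controls and 46.3 ± 37.2 CPM in icKO (SD, n = 5 and 5; exact two-sided permutation p = 0.238). In the 6 animals whose records agree it was 93.9 ± 8.73 CPM in controls and 19.9 ± 2.95 CPM in icKO (SD, n = 3 and 3), 4.72 times higher in controls, with an exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows. The gene goes against the label in the libraries of the 4 animals named above. Which part of the gene was floxed is not given in the sources used here, so the remaining transcript can include reads outside it.

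**Figure D1:**
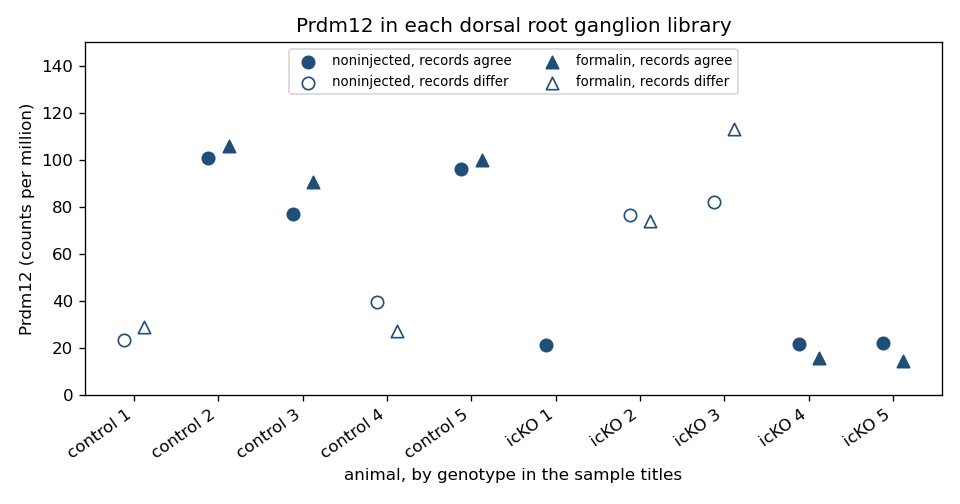
Prdm12 level (vertical axis, CPM of the library total) in the 19 libraries used, by animal as labelled (horizontal axis); circles are noninjected and triangles formalin libraries, and open symbols mark the 4 animals whose title and deposited name give different genotypes. The open symbols of control 1 and control 4 lie between 23.5 and 39.6 and those of icKO 2 and icKO 3 between 73.9 and 113.

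By label, no gene changed between icKO and control over the animal totals of all 10 animals. Each labelled group held animals at both levels of Prdm12, so this does not show that losing Prdm12 changes no gene. Trpv1, the capsaicin receptor, was at 154 ± 29.5 CPM in labelled icKO and 242 ± 33.5 CPM in labelled controls (SD, n = 5 and 5; log2 fold -0.69, SE 0.14), and its 2 groups of animals did not overlap. The same held for 247 of 19441 genes (1.27%, where chance gives 0.794%), but 21 of the 126 splits of the animals gave as many, and grouping by deposited name gave 789 (4.06%). The genes with the smallest p were Scel at log2 fold -1.45 (SE 0.24), Negr1 at -0.73 (SE 0.13) and Col11a1 at -0.50 (SE 0.09), and Heg1 at 0.50 (SE 0.09), Pthlh at 0.78 (SE 0.16) and Fgl2 at 0.65 (SE 0.14). None passed edgeR's quasi-likelihood test, where the smallest Benjamini-Hochberg adjusted p was 0.399 over 19441 genes. An unadjusted p under 0.05 was reached by 1815 genes, with 972 expected by chance, and DESeq2 called 67 genes.

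Lists of all 10 animals by label held no member past the threshold over all genes. Adjusted over the list alone, 6 of 10 peptidergic nociceptor genes were lower and 9 of 17 A-fibre mechanoreceptor and proprioceptor genes were higher in labelled icKO. As sets, these lists were called by camera with the preset correlation (Benjamini-Hochberg adjusted p = 1.2e-06 and 2.7e-07), and were not with an estimated correlation (adjusted p = 0.21 and 0.5). Of 31 lists, 14 were called with the preset correlation, 0 with an estimated one and 0 by fry. Beside these, all 14 skeletal muscle genes had a positive fold (median log2 fold 1.92), as did 8 of 8 erythroid genes (median 0.88). The muscle folds rest mainly on the icKO 5 formalin library, with a summed level of 2474 CPM. The other used icKO libraries were at 67.01 CPM or less.

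In the animal totals of the 6 agreeing animals, 109 genes rose and 62 fell in labelled icKO, of 19063 tested (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under the threshold of 0.05). Prdm12 fell, with a log2 fold of -2.26 (SE 0.09), and so did Chrnb4 (-3.20, SE 0.13) and Chrna3 (-2.49, SE 0.20), which encode nicotinic acetylcholine receptor subunits. Gal, the neuropeptide galanin, fell from 35.8 ± 2.22 to 10.7 ± 0.22 CPM (SD, n = 3 and 3), and Gfra3, the artemin co-receptor of peptidergic nociceptors, from 71.3 ± 7.22 to 32.1 ± 6.08 CPM. Adjusted p were 0.000192 for Prdm12 and Chrnb4, 0.00704 for Chrna3, 0.000913 for Gal and 0.00397 for Gfra3 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Further genes that fell were Uts2b (-4.23, SE 0.41), Mrgprb5 (-1.85, SE 0.18), Mrap2 (-1.41, SE 0.15), Otoa (-1.35, SE 0.13), Creg2 (-1.07, SE 0.11), the kainate receptor gene Grik1 (-1.02, SE 0.11) and Tmtc4 (-0.78, SE 0.09). In the animals left out, Chrnb4 was at 3.41 CPM in control 1, 18.1 in control 4, 6.24 in icKO 2 and 6.84 in icKO 3, and Gal at 13.6, 46.5, 18.9 and 19.4 CPM. Between these animals grouped by deposited name, without a sex term, some log2 differences went the other way. They were 1.89 for Uts2b, 1.01 for Chrna3, 0.9 for Mrap2, 0.38 for Gal and 0.26 for Chrnb4. The difference was -1.54 for Prdm12, -1.74 for Mrgprb5, -1.68 for Creg2, -1.37 for Otoa, -0.89 for Grik1, -0.35 for Tmtc4 and -0.06 for Gfra3.

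Among the genes that rose, Skor2, a transcriptional corepressor gene, went from 5.43 ± 0.76 to 21.1 ± 5.29 CPM (SD, n = 3 and 3; log2 fold 1.93, SE 0.13) and Ntrk3, the neurotrophin-3 receptor, from 324 ± 23.6 to 584 ± 40.1 CPM (0.85, SE 0.09). Agtr1a rose by 1.30 (SE 0.12), Stk32a by 1.25 (SE 0.12) and Mdga1 by 1.11 (SE 0.12) on the log2 scale. The other 7 named genes that rose lie next to Avil, the advillin gene, in gene order. They were March9 (1.65, SE 0.13), Tsfm (1.63, SE 0.11), Mettl1 (1.49, SE 0.13), Atp23 (1.22, SE 0.12), Ctdsp2 (1.19, SE 0.10), Tspan31 (1.18, SE 0.09) and the cell cycle kinase gene Cdk4 (1.13, SE 0.08), while Avil itself was at 0.09 (SE 0.16). Adjusted p ran from 0.00253 (Tsfm) to 0.0103 (Atp23) for these 7 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Leaving out an animal moved the count of 171 to 568 (control 2), 8 (control 3), 29 (control 5), 621 (icKO 1) or 34 (icKO 4), and 6 genes, Chrnb4, Gal, March9, Prdm12, Skor2 and Tsfm, were called in each of the 6 fits. The count was 1036 with DESeq2, 1880 without a filter, 33 without the sex term and 1391 without the icKO 5 formalin library.

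**Figure D2:**
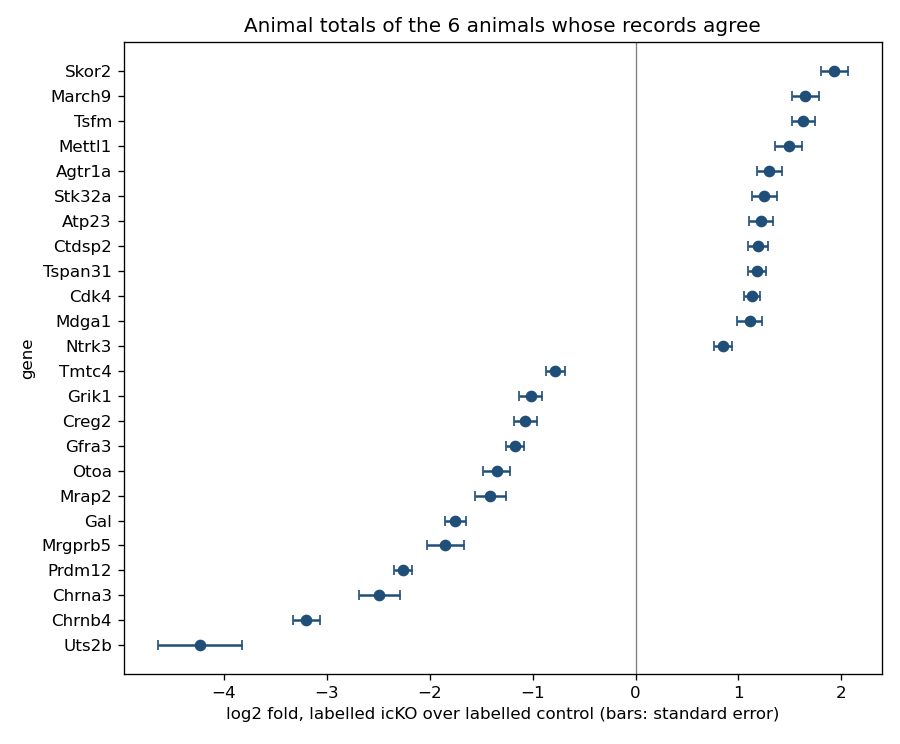
Log2 fold (horizontal axis) of the 24 named genes (vertical axis) between labelled icKO and labelled control animals, in animal totals of the 6 agreeing animals; points are edgeR estimates and bars standard errors. Skor2 is highest at 1.93 and Uts2b lowest at -4.23.

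**Figure D3:**
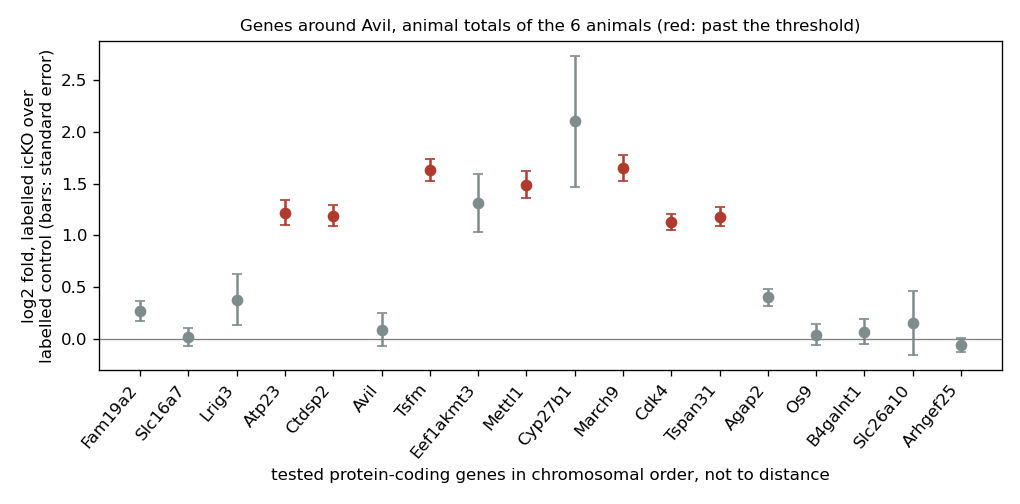
Log2 fold between labelled icKO and labelled control (vertical axis, animal totals of the 6 agreeing animals) for tested protein-coding genes in their order along the chromosome around Avil (horizontal axis, not to distance); bars are standard errors and red points passed the threshold. The 7 red points lie between 1.13 and 1.65, and Avil is at 0.09.

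Of 10 peptidergic nociceptor genes 3 fell, Gfra3, Adcyap1 (-0.67, SE 0.10) and Trpv1 (-0.78, SE 0.12), and of 17 A-fibre mechanoreceptor and proprioceptor genes 3 rose, Ntrk3, Runx3 (0.97, SE 0.15), a transcription factor gene of proprioceptors, and Kcns1 (0.83, SE 0.13). Adjusted over the list alone these counts were 5 and 8, and as sets both lists had adjusted p = 0.75 with an estimated correlation. With all 10 animals grouped by deposited name instead, 0 of 10 peptidergic genes were lower (median log2 fold -0.19) and 1 of 17 A-fibre genes was higher (median 0.16). Between the 4 left-out animals grouped that way, the log2 difference was -0.06 for Gfra3, 0.30 for Adcyap1, 0.48 for Trpv1, 0.36 for Ntrk3, -0.23 for Runx3 and -0.05 for Kcns1. This sets a female and a male against females only, with no sex term. Trpv1 was at 199 and 286 CPM in the left-out animals labelled control 1 and 4, and at 160 and 179 CPM in icKO 2 and 3. The totals of the 6 animals mix both agents. In CPM of the library total, noninjected Trpv1 was 241, 175 and 168 in control 2, 3 and 5. It was 170, 166 and 145 in noninjected icKO 1, 4 and 5. With formalin it was 277, 269 and 352 in these controls, and 101 and 93 in icKO 4 and 5. Of 30 nociceptor ion channel genes Trpv1 and P2rx2 (-1.12, SE 0.18) fell and Hcn2 (0.76, SE 0.08) rose. Of 25 sensory neuron transcription factor genes Prdm12 fell and Hoxd1 (0.84, SE 0.12) and Runx3 rose, and Prdm12 was the only one past the threshold of 14 PRDM family genes. Of 12 non-peptidergic genes Mrgprb5 fell, and of 22 nerve injury genes Gal and Ecel1 (-2.23, SE 0.37) fell and Jun (0.77, SE 0.09) rose. Adjusted over the list alone, 2 nociceptor ion channel genes were higher and 4 lower, 9 transcription factor genes were higher and 1 lower, and 1 nerve injury gene was higher and 4 lower. With all 10 animals grouped by deposited name, 1 ion channel gene was higher and 1 lower over all genes. In that grouping 0 transcription factor genes were higher and 1 lower, and 1 nerve injury gene was higher and 0 lower. Single members past the threshold were Fkbp5 (0.69, SE 0.11) of 18 heat shock and stress genes and Ncmap (-0.57, SE 0.09) of 17 Schwann cell genes.

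No member passed in the other lists between these 6 animals. These were pruriceptor (12 tested, median log2 fold -0.09), C-low-threshold mechanoreceptor (7, -0.04), cold thermoreceptor (6, -0.72), opioid and other inhibitory receptor (18, 0.08), visceral neuron fate (3, 0.34), immediate-early (22, 0.05), cytokine and inflammatory mediator (22, 0.22), interferon response (17, 0.20) and macrophage (17, 0.18) genes. The same holds for neutrophil (12, 1.49), lymphocyte (13, 1.01), satellite glia (14, 0.09), endothelium (12, 0.19), fibroblast and connective tissue (14, 0.74), pericyte and smooth muscle (10, 0.32), skeletal muscle (14, 3.28), central nervous system (6, 0.07), adipocyte (9, 1.74), cartilage and bone (7, -0.05), erythroid (8, 1.86), proliferation (12, 1.31) and mitochondrially encoded (8, -0.14) genes. Adjusted over the list alone, 4 cold thermoreceptor genes were lower, and 6 erythroid, 6 lymphocyte, 3 proliferation and 2 fibroblast genes were higher. The skeletal muscle median of 3.28 rests mainly on icKO 5, whose formalin library had a summed level of 2474 CPM. Camera with the preset correlation called 13 of 31 lists, among them peptidergic nociceptor (lower, Benjamini-Hochberg adjusted p = 0.00057), A-fibre (higher, 5.3e-06), erythroid (higher, 1e-06) and proliferation (higher, 3.8e-06). With an estimated correlation each of these had adjusted p = 0.75, and neither that setting nor fry's test of movement in one direction called any list. Fry's test of movement in either direction called some lists, such as nociceptor ion channel (adjusted p = 0.00042). It did not call others, such as neutrophil (adjusted p = 0.35).

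Within the noninjected libraries of the 6 animals, 676 genes rose and 155 fell in labelled icKO of 17669 tested. Prdm12 was at 90.8 ± 12.1 CPM in controls and 23.0 ± 0.801 CPM in icKO (SD, n = 3 and 3; log2 fold -1.97, SE 0.10; adjusted p = 1.81e-06 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Tsfm (1.75, SE 0.13), Cdk4 (1.05, SE 0.09), Tspan31 (1.20, SE 0.10), Skor2 (2.40, SE 0.21) and March9 (1.88, SE 0.18) rose, and Otoa (-1.27, SE 0.14), Creg2 (-1.04, SE 0.12), Smr2 (-1.73, SE 0.22) and Grik1 (-0.87, SE 0.11) fell. Of 24 sensory neuron transcription factor genes 8 rose and 1 fell, and of 17 Schwann cell genes 3 fell; adjusted over the list alone these were 16, 1 and 5. Camera with the preset correlation called both lists (Benjamini-Hochberg adjusted p = 5.3e-05 and 0.0017), and with an estimated correlation they had adjusted p = 0.69 and 0.76. Beside these, 8 of 8 erythroid genes had a positive fold (median 1.32), 7 of them past the threshold adjusted over the list alone, and 9 of 9 adipocyte genes had a positive fold (median 1.75, 0 past it adjusted over the list alone). Mitochondrially encoded genes had a negative fold in 8 of 8 (median -0.56) and macrophage genes in 17 of 17 (median -0.32). Camera with the preset correlation called these 4 lists (Benjamini-Hochberg adjusted p = 5.3e-05, 0.0017, 0.0017 and 0.023), with adjusted p = 0.76, 0.76, 0.76 and 0.93 with an estimated correlation. The count of 831 became 17 without control 2, 21 without control 3, 64 without control 5, 74 without icKO 1, 2046 without icKO 4 and 1282 without icKO 5, 1479 in a fit of these libraries alone, 1542 with DESeq2, 2033 without a filter and 2128 without the icKO 5 formalin library. By label over all animals no gene passed (1538 at an unadjusted p under 0.05; DESeq2 called 1).

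Within the formalin libraries of the 6 animals, 3 control and 2 icKO, 1118 genes rose and 497 fell in labelled icKO (edgeR's quasi-likelihood test). Prdm12 (-2.66, SE 0.12), Gal (-2.32, SE 0.21), Gfra3 (-1.81, SE 0.16), Trpv1 (-1.55, SE 0.16) and Grik1 (-1.27, SE 0.13) fell, and Ctdsp2 (1.47, SE 0.13), Cdk4 (1.29, SE 0.10), Tspan31 (1.14, SE 0.11), the erythrocyte enzyme gene Bpgm (1.49, SE 0.13) and Car2 (1.18, SE 0.11) rose. Of 10 peptidergic nociceptor genes 6 fell, and of 30 nociceptor ion channel genes 8 fell (7 and 11 adjusted over the list alone). In the noninjected libraries of these animals 1 peptidergic gene rose and 1 fell (median log2 fold -0.14), and 3 ion channel genes rose and 1 fell (median 0.23). Camera gave these lists Benjamini-Hochberg adjusted p = 0.32 and 0.013 at the preset correlation and adjusted p = 0.87 and 0.76 with an estimated correlation. Erythroid genes rose in 8 of 8, proliferation genes in 11 of 12, lymphocyte genes in 6 of 13 and macrophage genes in 5 of 17 (8, 11, 10 and 9 adjusted over the list alone). The peptidergic, ion channel, erythroid and proliferation lists were called by camera with the preset correlation (Benjamini-Hochberg adjusted p = 9.3e-07, 8.4e-07, 2.8e-11 and 5.1e-10) and not with an estimated correlation (adjusted p = 0.17, 0.31, 0.17 and 0.2), while fry, which tests movement in one direction, called 9 of 30 lists. In the library labelled icKO 4 formalin, S100a8 of neutrophils stood at 728 and the globin Hba-a1 at 191 CPM, and in icKO 5 formalin at 410 and 234, with Acta1 of skeletal muscle at 225. The count of 1615 became 322 without control 3, 139 without control 5, 3360 without icKO 4, 1024 without the icKO 5 formalin library, 991 in a fit of these libraries alone and 3170 without a filter. By label over all animals no gene passed (2222 at an unadjusted p under 0.05; DESeq2 called 15).

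No gene changed with formalin when the libraries of both genotypes were pooled, 9 formalin and 10 noninjected. The nerve injury gene Atf3 was at 14.5 ± 4.32 CPM with and 9.83 ± 4.11 CPM without formalin (SD, n = 9 and 10; log2 fold 0.56, SE 0.19), and Sox11 at log2 fold 0.29 (SE 0.11). The immediate-early gene Junb was at -0.30 (SE 0.13), the interferon-induced gene Bst2 at -0.38 (SE 0.13) and the myelin gene Cldn19 at -0.30 (SE 0.09). The genes with the smallest p were Steap1 (0.68, SE 0.17), Zc4h2 (0.19, SE 0.05), Myh1 (4.75, SE 1.37), Nog (-0.79, SE 0.18), Ier5l (-0.54, SE 0.12) and Tpst2 (-0.25, SE 0.07). None passed edgeR's quasi-likelihood test (smallest Benjamini-Hochberg adjusted p = 0.971; 478 genes at an unadjusted p under 0.05 of 17275 tested; DESeq2 called 0). Camera with the preset correlation called 8 of 30 lists, among them interferon response genes, lower with 16 of 17 folds negative (adjusted p = 1.5e-06), and Schwann cell genes, lower with 15 of 17 negative (7.6e-05). With an estimated correlation both had adjusted p = 0.81. Beside these, folds were positive in 13 of 13 skeletal muscle genes (median log2 fold 2.25) and 7 of 7 mitochondrially encoded genes (0.19), and negative in 8 of 9 adipocyte genes (-0.72). Summed levels of skeletal muscle genes were 2474 CPM in icKO 5 formalin and 427.8 CPM in control 4 formalin. The other used formalin libraries were at 27.1 to 56.13 CPM, so the muscle folds rest mainly on these 2 libraries.

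Formalin changed no gene within labelled controls, neither over all animals (570 genes at an unadjusted p under 0.05; DESeq2 called 0) nor in the 6 agreeing animals (733; DESeq2 called 5) by edgeR's quasi-likelihood test. Within labelled icKO no gene passed over all animals (934, and DESeq2 called 0), nor did any within icKO with all animals grouped by deposited name. In the agreeing icKO animals, 3 noninjected and 2 formalin libraries, 250 genes rose and 198 fell. With DESeq2 these were 888 and 1042, and without the sex term 861 and 985. All of these numbers rest on the icKO 4 and icKO 5 formalin libraries described above, both of them from males. The leukocyte gene Plek (1.05, SE 0.12), Bpgm (1.00, SE 0.13), Stk17b (1.37, SE 0.19), Fam111a (1.18, SE 0.15) and the immunoglobulin segment Igkv1-135 (2.12, SE 0.28) rose, and Shf (-0.97, SE 0.13), Zdhhc22 (-0.75, SE 0.11), Csdc2 (-0.83, SE 0.13), Unc5b (-1.17, SE 0.19), Zfhx2 (-0.77, SE 0.13) and Prdm12 (-0.58, SE 0.12) fell. Of 30 nociceptor ion channel genes 5 fell, and of 8 erythroid genes 2 rose (15 and 8 adjusted over the list alone), both called by camera with the preset correlation (Benjamini-Hochberg adjusted p = 1.6e-07 and 2.2e-07) and at adjusted p = 0.34 with an estimated correlation. Folds were positive in 13 of 13 skeletal muscle genes (median log2 fold 5.21), 8 of 8 mitochondrially encoded genes (0.72), 17 of 17 macrophage genes (1.09) and 12 of 12 neutrophil genes (1.88). Of these, 13, 7, 5 and 0 were higher adjusted over the list alone. The muscle folds rest mainly on the icKO 5 formalin library, with a summed level of 2474 CPM. It was 56.13 CPM in icKO 4 formalin and 21.37 to 52.73 CPM in the noninjected libraries of these animals. With the animal as a block the count of 448 was 1187, and it was 147 without the icKO 5 formalin library. Leaving out control 2, control 3, control 5, icKO 1, icKO 4 or icKO 5 gave 0, 1, 25, 12, 3847 and 139.

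The formalin effect differed between labelled genotypes for 65 genes in the 6 animals, 41 more positive and 24 more negative in icKO. Plek (1.22, SE 0.17), Ccl9 (2.15, SE 0.30), Cd53 (2.18, SE 0.31), Stk17b (1.80, SE 0.26) and Mpeg1 (1.72, SE 0.25), of which Cd53 and Mpeg1 are leukocyte and macrophage genes, had the smallest p among the positive ones. Trpv1 (-1.38, SE 0.20), Htr3a (-0.98, SE 0.16), Adcy2 (-1.05, SE 0.17), Shf (-1.10, SE 0.17) and Zdhhc22 (-0.95, SE 0.15) did among the negative ones. Adjusted p ran from 0.0362 to 0.0384 for these 10 genes in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With the animal as a block the count was 1057, and it was 0 without control 2, control 3, control 5 or icKO 1, 3547 without icKO 4 and 154 without icKO 5. Over all animals by label 0 genes passed (922 at an unadjusted p under 0.05, and DESeq2 called 0). Grouped by deposited name, 0 passed as well.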

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

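Both tests of other cells in the formalin icKO libraries were chosen only after the result was seen.

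Of 36 values of labelled groups checked for a library far from the rest of its group, 5 stood apart. The rule gives about 1 in 20 for independent values with a normal spread. These values come from the same libraries and were not checked for such a spread, so that rate cannot be set against the 5. The library labelled control 1 formalin held 22392635 counts, against 11763893 to 14747939 in the other control formalin libraries. The library labelled icKO 1 formalin held 2829 counts, against 19497710 to 20076525 in the others of its group. Summed levels of skeletal muscle genes were 427.8 CPM in the library labelled control 4 formalin (31.97 to 46.84 in the others) and 2474 CPM in icKO 5 formalin (27.1 to 56.13). Summed levels of neutrophil genes were 1306 CPM in the library labelled icKO 4 noninjected (273 to 562.4).

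The formalin effect differed between labelled genotypes for 65 genes in the 6 animals whose records agree, by a test of the difference itself, and formalin moved 448 genes in the icKO among them. All 45 tested skeletal muscle, erythroid, neutrophil and proliferation genes had a positive fold there (100%), but these lists were picked because the libraries were high in such transcripts (Acta1 225 CPM in icKO 5 formalin, S100a8 728 CPM in icKO 4 formalin) and 43 of the 45 were also over 1 CPM in noninjected controls (0 are in another list), so the share decides nothing and muscle, blood and marrow cells stay an open source of the genes that rose. For genes that fell, the median log2 fold was -0.43 (MAD 0.4) for nociceptor ion channels and -0.29 (MAD 0.42) for A-fibre genes. The MAD is that of single genes and gives no error for their difference of -0.14, so with 2 formalin icKO libraries dilution by other cells and a fall in nociceptors cannot be told apart. A response of the icKO ganglia to formalin stays open, and the 448 genes became 0 without control 2. Control 2 and icKO 1 were the only females of these 6 animals. Without control 2, the sex term takes up the 1 used library of icKO 1, so that fit loses icKO 1 as well.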

How the results depend on the processing

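Fits with the small icKO 1 formalin library and fits without the icKO 5 formalin library were chosen after seeing the data. The cause of the changes below was not tested, except that fits leaving out animals hold fewer samples and that without a filter genes with few counts enter the tests. At 2829 counts the small library gives no usable level for single genes.

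For icKO against control in animal totals of the 6 agreeing animals, the 171 genes became 1036 with DESeq2 (168 shared), 1880 without a filter (171 shared), 33 without the sex term (33 shared) and 1391 without the icKO 5 formalin library (166 shared). Leaving out an animal gave 8 (control 3) to 621 (icKO 1). In their noninjected libraries the 831 genes became 1542 with DESeq2, 2033 without a filter, 1479 with only the groups compared and 2128 without the icKO 5 formalin library, and 17 (without control 2) to 2046 (without icKO 4). In their formalin libraries the 1615 genes became 3170 without a filter, 991 with only the groups compared and 1024 without the icKO 5 formalin library, and 139 (without control 5) to 3360 (without icKO 4). Leaving out icKO 4 or icKO 5 leaves 1 formalin icKO library, assumed to vary like the other groups.

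For formalin within the agreeing icKO animals the 448 genes became 1930 with DESeq2, 3155 without a filter, 1846 without the sex term, 1016 with limma-voom, 1261 with the small library and 147 without the icKO 5 formalin library, and 0 (without control 2) to 3847 (without icKO 4). The 65 genes of the interaction became 1316 with DESeq2, 2728 without a filter, 109 with limma-voom and 604 with the small library, and 0 (without control 2) to 3547 (without icKO 4). For formalin within the agreeing controls, 0 became 5 with DESeq2 and 185 without a filter, and 0 in each fit leaving out an animal.

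By label over all animals, counts of 0 became 67 (DESeq2) and 851 (no filter) for animal totals, 1 and 490 for noninjected and 15 and 1274 for formalin libraries. Without a filter they were 81 for formalin within controls, 550 within icKO and 423 for the interaction. Leaving out an animal gave 0 to 11 for animal totals (11 without control 1), 0 to 1 for formalin libraries, and 0 in the other comparisons by label. The pooled formalin count was 0 in every alternative run.

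With the animal as a replicate block, pairing its formalin and noninjected libraries, the counts were 1187 for formalin within the agreeing icKO animals, 1057 for the interaction and 1 for formalin within the agreeing controls, and no other count of formalin calls moved. A block on the title number across genotypes left the counts by label at 0; libraries sharing a number correlated at -0.01 to 0.31 (noninjected) and -0.22 to 0.39 (formalin).

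Prdm12, not past the threshold in these comparisons, changed sign in 7 fits. Under the animal block its log2 fold was -0.15 for formalin within icKO, -0.18 for the interaction and -0.05 pooled. Leaving out animals gave -0.02 to 0.13 for formalin within controls, -0.07 to 0.39 within icKO and -0.13 to 0.33 for the interaction, all by label. Of 994 checks of called named genes 837 stayed past the threshold, 157 did not and 0 changed direction. Of 890 checks of named genes that had not passed, 96 passed.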

Other observations

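Chosen only after the result was seen were the tests of the genes next to Avil, of chance clustering and transgene copies, of the number of calls by deposited name, of a structure other than genotype, and the splits of the noninjected libraries and of formalin within controls in the 6 animals.

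Pruriceptor, C-low-threshold mechanoreceptor and cold thermoreceptor lists leaned lower in animals labelled icKO over all 10 animals, with 0 members past the threshold over all genes, while the non-peptidergic nociceptor list did not (6 of 12 folds negative, median log2 fold -0.01, camera adjusted p = 0.95). Folds were negative in 11 of 12 pruriceptor genes (median log2 fold -0.18), 6 of 7 C-low-threshold mechanoreceptor genes (-0.19) and 5 of 6 cold thermoreceptor genes (-0.38), where 0, 3 and 0 were lower adjusted over the list alone. Camera with the preset correlation called these lists (Benjamini-Hochberg adjusted p = 0.015, 0.004 and 0.026), and with an estimated correlation they had adjusted p = 0.56, 0.21 and 0.56. With the 10 animals grouped by deposited name, the medians of these lists were 0.07, 0.01 and -0.34, so the first 2 lost the lean. In the noninjected libraries of the 6 agreeing animals the medians of these lists were 0.09, 0.09 and -0.18, with 1 pruriceptor gene rising and, adjusted over the list alone, 3 C-low-threshold mechanoreceptor genes higher. In the formalin libraries of these animals they were -0.29, -0.29 and -1.67, with 1, 1 and 2 genes falling, but there non-peptidergic genes were negative in 12 of 12 as well, erythroid genes rose in 8 of 8 and skeletal muscle folds were positive in 13 of 13.

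The titles and the deposited names give different genotypes for the animals labelled control 1, control 4, icKO 2 and icKO 3. Prdm12 placed 4 of these 4 nearer the mean of the genotype in the deposited name, and so did the mean level of the genes next to Avil (4 of 4; 5.72 and 5.73 log2 CPM in control 1 and 4, 4.35 and 4.37 in icKO 2 and 3), while the score over the 171 genes called between the other 6 animals placed 3 of 4, with control 4 at -0.14 on the control side. Grouped by deposited name, animal totals gave 209 genes (114 higher, 95 lower, 57 shared with the 171). The other 99 drawn splits gave at most 3. Wrong titles are thus a candidate explanation that Prdm12, the genes next to Avil and this count go with. Only the score leaves it open, for control 4, whose Prdm12 (5.03 log2 CPM) and genes next to Avil lay nearer the agreeing icKO animals. Of the 171 genes, 61 (35.7%) moved the opposite way in the 4 animals grouped by deposited name, among them 31 of the 62 that were lower. That comparison sets control 1 (female) and control 4 (male) against icKO 2 and 3 (both female) without a sex term, so sex, noise and a structure such as litter, cage or day cannot be told apart.

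Genes next to Avil rose together in labelled icKO of the 6 agreeing animals, with 7 called among 11 neighbouring tested genes. In 10000 random placements of the 100 called genes among 15423, at most 5 were called in a window. The share with as many is thus set at its floor of 1e-04, which argues against chance clustering of these 7 genes. Their mean log2 fold was 1.39 in noninjected and 1.31 in formalin libraries, a difference of -0.08, but they were called on totals of these same libraries, so this does not tell extra gene copies carried by an Avil-CreERT2 transgene (the characteristics name AdvCreERT2) from any other stable difference between the animals. Avil itself was at 0.09 (SE 0.16). Whether CreERT2 was inserted at Rosa26, which the series text names, stays open (Gt(ROSA)26Sor -0.24, SE 0.25, adjusted p = 0.629 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). That fold bears on the Cre line and not on why the genes next to Avil rose. An effect of Prdm12 loss on the genes next to Avil also stays open, since no group carried the Cre with intact Prdm12.

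In the comparisons by label edgeR called 0 genes, so every split gives as many by construction and the number of such splits says nothing about chance. They were 100 of 100 splits for animal totals (highest other 209), 70 of 70 for noninjected (1504), formalin (697) and interaction (0), 70 of 70 for formalin within controls (26) and within icKO (2941), and 70 of 70 swaps within animals for the pooled comparison (0). The splits with 209, 1504 and 697 genes are the same grouping, the animals labelled control 2, 3, 5, icKO 2 and icKO 3 against the rest, which is that of the deposited names and points to a structure of the samples. The split with 2941 genes sets the formalin library of icKO 3 and the noninjected ones of icKO 1, 4 and 5 against the rest, which also points to a structure of the samples. For the 6 agreeing animals 10 splits are too few for a share under 0.05. Only the labelled split itself, 1 of 10, gave as many as the 171 genes of the animal totals (highest other 60). The same held for the 831 genes of the noninjected libraries (1 of 10, highest other 0). For formalin within their controls, with 0 genes called, 10 of 10 gave as many (highest other 0), which again holds by construction.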
